A study of Mus musculus with 8 samples.

How the data were processed

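Gene expression was measured with 1-colour (Cy3) microarrays in 8 pooled RNA samples of mice of mixed C57BL/6 and 129 background, 1 array per sample, per the labels. The mTEC samples were sorted as live CD45-negative cells that stained for Epcam and UEA1 and were high for CD80 and MHC class II, from digested thymi pooled in groups of 4 to 6, per the labels. The small intestine samples pooled epithelial cells of 3 mice each, per the labels. The design text speaks of 3 replicates in each group. For small intestine 1 array of each genotype was analysed, replicate 1 labelled Cdx1+/+ and replicate 2 labelled Cdx1-/-. Whether other intestine arrays were made is not given in the sources used here. RNA extraction and labelling were done by a service company, per the labels.

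The deposited scanner files hold linear intensity values per spot, made by the authors with Agilent Feature Extraction (named in the submitters' processing notes) version 10.7.3.1, per the file headers. The processed intensity in these deposited files is background-subtracted and detrended within each array, and is not normalized between arrays, per the file headers. The deposited table of normalized values was compared with the scanner files: each of its 8 columns is the processed intensity of its own array times 1 constant, on a linear scale, with a median of 1 in every column. How the authors chose that scaling is not given in the sources used here. Probe positions are those of the files, on the mouse build mm9.

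From the scanner files, 59305 non-control spots of 55681 probes were read. Spots flagged as outliers were dropped, which removed 12 probes, and 55669 were used. Processed intensities were put on the log2 scale, the array's 75th percentile was subtracted, and spots of a probe were averaged. Gene names came from the accession of the probe through a reference gene table (GRCm38.p6, used for names only) for 27500 probes. A further 3554 probes kept a file name that the table also holds, and 24615 kept the file's own name. In all there were 34963 gene names, of which 19629 are ordinary symbols, and the rest are counted without being named. Each gene was represented by its brightest probe among those well above background on at least 2 arrays of 1 group, or on the array itself for a group of 1 array.

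Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the R package data.table (version 1.17.8), pandas 2.3.3 and matplotlib 3.10.9 for tables and plots. All tests were 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Cdx1-/- and Cdx1+/+ mTEC were compared with the 6 mTEC arrays. Tissues were compared with all 8 arrays and genotype as an additive term. The small intestine pair has 1 array per genotype, so its differences are values without a test, and a list's median is placed among 10000 random lists of the same size matched on mean expression in 20 bins. The difference between the tissues' contrasts was not tested. A probe that was well above background on no array of a group has only a bound there, and where it was so on some arrays but not all the fitted value is given with their number. Its fold is given as "at least", the bright group's mean against, per array of the dim group, the higher of the probe's own value and the lowest value among probes well above background.

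Before the data were examined, 31 gene lists with 614 entries were fixed, of which 602 are on the array. A list was tested in mTEC when at least 5 members were measured, which held for 28 lists. The test was camera with a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Intestine-enriched genes were those at least 8-fold higher in the mean of both intestine arrays than in the mean of the mTEC arrays and well above background on both, and genes near Cdx1 were those within 10 Mb of its probe. The rule for naming genes was fixed at the same time. It takes the 12 higher and 12 lower genes of largest change among those that passed the test with all arrays of the groups apart, the 12 of largest fold per direction between tissues and in the intestine pair, the Cdx paralogs, and up to 4 members of smallest p of each list. In the intestine pair the list examples are those of largest difference. Genes chosen otherwise are said to be, and some genes that the rule takes are not reported here.

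Slides were read from the array barcodes. The scanning sessions part the arrays as the slides do. Slide 1 held 5 arrays, the 3 Cdx1+/+ mTEC arrays and Cdx1-/- mTEC replicates 2 and 3. Slide 2 held 3 arrays, Cdx1-/- mTEC replicate 1 and both intestine arrays. Slide was fitted as a block and the mTEC comparison was repeated within slide 1, which is the same fit as leaving out Cdx1-/- replicate 1. Within slide 2 the tissues differ with no array left to give a spread. Replicate numbers came from the sample titles. Deviations from the group means correlated by 0.322, 0.147 and 0.148 between mTEC samples of the same number, and by −0.222 to 0.0555 between others. The numbers may therefore pair the samples. The main fit had no term for pairing, and a fit with the replicate number as a block was run as an alternative.

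The other alternatives were quantile normalization, normexp background correction with an offset of 50 on the raw and background intensities, the authors' normalized table, no filter and a stricter filter on dim probes, the mean of a gene's probes, array weights, each array left out in turn, other windows and enrichment thresholds, all 8 arrays in 4 groups, a trended robust variance, and a plain 2-sample test. The steps were tested on simulated data built from the real arrays. For mTEC, with 24338 genes and 10 runs, 27.3% of simulated 1.5-fold changes, 62.4% of 2-fold changes and 90.9% of 4-fold changes were recovered, and 5.64% of calls were unchanged genes. For the tissue comparison, with 25273 genes, 84.5% of simulated 4-fold changes were recovered and 5.74% of calls were unchanged genes. Only 200 genes were changed in each run, with a list of 30 more for mTEC, and each gene was drawn independently of the others. Far more genes were called on the real arrays, so these rates need not hold there. The number of arrays limits the precision. Each replicate is a pool of several mice, so p-values measure the spread between pools. No reference genome was used here.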

Results

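Expression was profiled on 8 arrays. Mature medullary thymic epithelial cells (mTEC), the stromal cells that display proteins of many organs to developing T cells, gave 6 of them, with 3 Cdx1+/+ and 3 Cdx1-/- samples. Small intestine epithelial cells (SIEC) gave 2, 1 labelled Cdx1+/+ and 1 labelled Cdx1-/-. Cdx1 is a caudal-type homeobox transcription factor of the intestinal epithelium, and the series title gives the question as how its loss alters ectopic gene expression in mTEC. Of 59305 non-control spots, 63.5%, 59.1% and 61.2% were well above background on the Cdx1+/+ mTEC arrays, and 58.6%, 59.2% and 59.0% on the Cdx1-/- mTEC arrays. The intestine arrays had 46.3% (labelled Cdx1+/+) and 44.6% (labelled Cdx1-/-), and no spot was saturated. Pearson correlations of log2 signals across probes were at least 0.988 between mTEC arrays of 1 genotype, 0.985 to 0.987 between genotypes, 0.982 between the intestine arrays and 0.832 to 0.836 between tissues. Levels are log2 signals relative to the 75th percentile of the array.

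Cdx1 transcript fell in Cdx1-/- mTEC but remained well above background. Its probe, on chromosome 18 from 61178558 to 61178617 (mm9), read 6.13 ± 0.05 (SD, n = 3) in Cdx1+/+ and 5.15 ± 0.10 (SD, n = 3) in Cdx1-/- mTEC. That is a log2 difference of −0.98 with a standard error of 0.09 (limma, adjusted p = 0.00326), and −0.93 within slide 1 (adjusted p = 0.0115). Cdx2, the paralog that drives intestinal identity, also fell, from −0.16 ± 0.12 to −1.001 ± 0.21 (SD, n = 3 each), a log2 difference of −0.84 with a standard error of 0.13 (adjusted p = 0.0123). Cdx4 was not well above background on any of the 8 arrays. The intestine pair went the other way at Cdx1, with 5.13 on the array labelled Cdx1+/+ and 6.73 on the array labelled Cdx1-/-, a log2 difference of 1.60 (1.502 after quantile normalization and 1.39 in the authors' table). Cdx2 read 5.70 and 5.45 on them. Which part of Cdx1 the allele lacks is not given in the sources used here. The probe lies near the 3' end of the transcript, so it checks the labels little if that end was kept, and directions in intestine are given by label throughout.

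**Figure D1:**
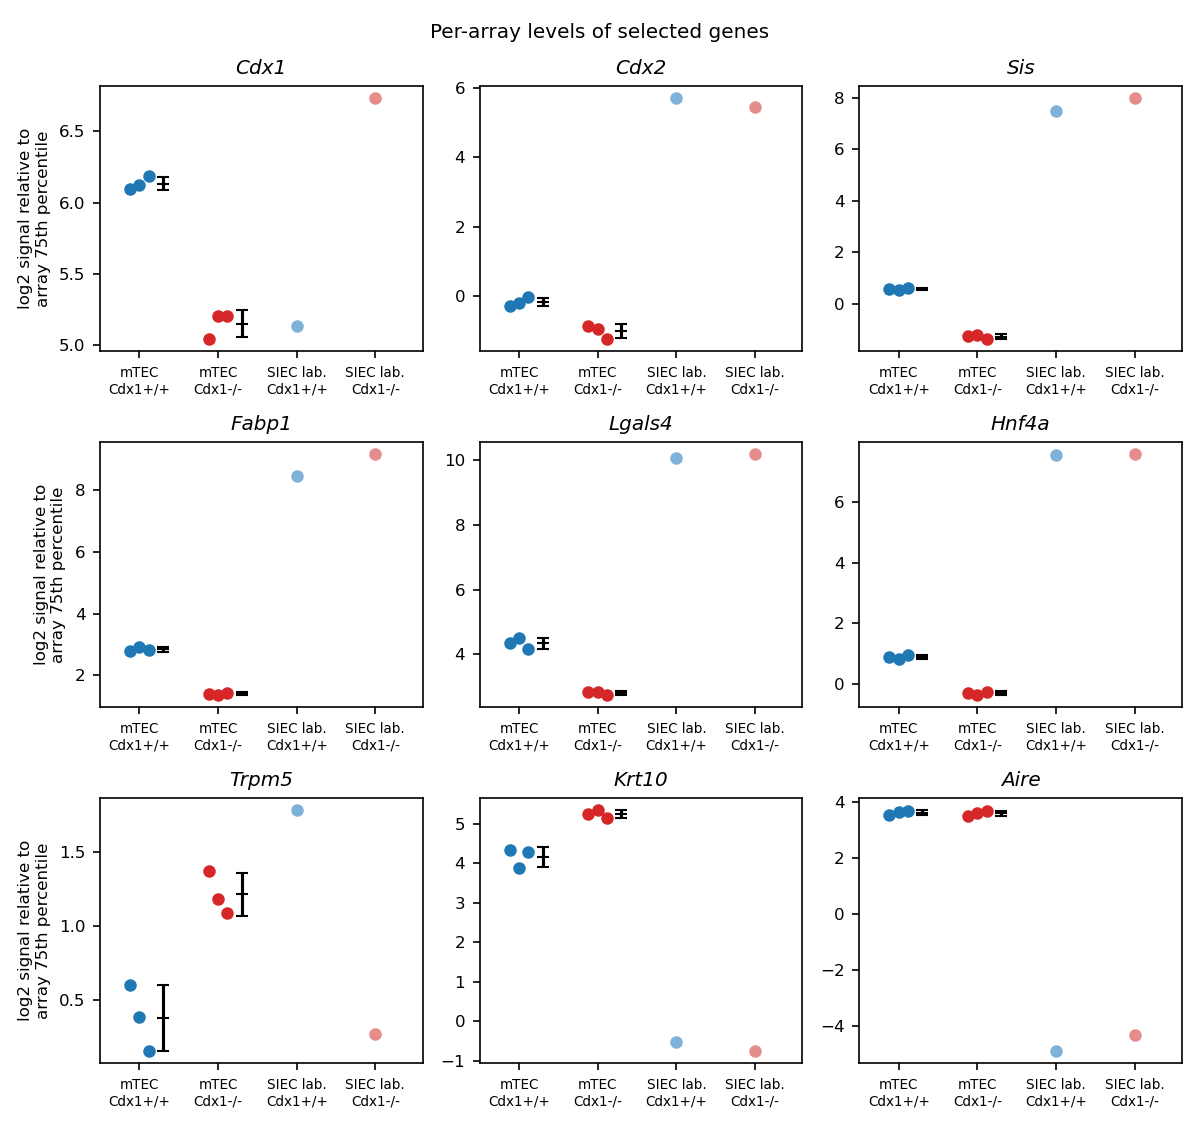
Log2 signal relative to the array's 75th percentile (y axis, a scale of its own in each panel) for 9 genes on each array, with blue points for Cdx1+/+ and red points for Cdx1-/- samples, paler for the single intestine arrays by label, and bars for the mean ± SD of the 3 mTEC arrays of a genotype. Cdx1 reads 6.13 and 5.15 as means of Cdx1+/+ and Cdx1-/- mTEC, and the 3 arrays of each genotype lie apart for every gene shown except Aire.

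The Cdx1-/- genotype went with changes of both signs across the mTEC transcriptome. Slc6a7, a proline transporter of brain, lies next to Cdx1 on chromosome 18 (61155375 to 61155434) and fell by 2.80 on the log2 scale (SE 0.11, adjusted p = 0.00104), which is 6.94-fold. Fabp9, a testis fatty acid-binding protein on chromosome 3 (10194055 to 10194721), fell by 2.22 (4.67-fold, adjusted p = 0.00154). Tm4sf20, a tetraspanin-like membrane protein, fell by 2.13, the brush border protocadherin Cdhr5 by 2.10, the metalloproteinase Adam19 by 2.04, and the sialic acid-binding lectin Siglec15 by 2.03. The ephrin receptor gene Epha3 fell by a fitted 2.84, a size that rests in part on background, since only 1 of the 3 Cdx1-/- arrays was well above it. Cep76, which encodes a centrosomal protein, was at least 3.87-fold lower (adjusted p = 0.0020), and was not well above background on any Cdx1-/- array. The same held for the gasdermin gene Gsdmcl2 (at least 1.91-fold), the aldolase gene Dera (at least 1.37-fold), Clrn3 (at least 1.21-fold, 2 of 3 Cdx1+/+ arrays above background) and the odorant receptor gene Olfr1370, for which no fold is given.

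Among the genes that rose, Hoxa3, a homeobox gene needed to form the thymus (chromosome 6, 52119087 to 52119146), went from −2.53 ± 0.20 to −0.83 ± 0.22 (SD, n = 3 each), a log2 difference of 1.69 (SE 0.15, adjusted p = 0.00336). The noncoding RNA Pantr1 rose by 1.72 (3.30-fold) and the secreted-protein gene Bpifa3 by 1.71 (3.28-fold). Several risers were not well above background on any Cdx1+/+ array: the fatty acid transport gene Slc27a6 (at least 3.94-fold), Aadacl2 (at least 3.32-fold), Dbpht2 (at least 2.65-fold), the testis histone gene H2al1j (at least 2.16-fold) and Katnal2 (at least 1.94-fold, on chromosome 18 from 77231939 to 77231983). So were the bitter taste receptor genes Tas2r117 (at least 2.38-fold) and Tas2r105 (at least 1.31-fold), and the vomeronasal receptor gene Vmn2r42 (at least 1.65-fold), the last 2 above background on 2 of 3 Cdx1-/- arrays. Zfp94 rose by 1.44 (adjusted p = 0.0311), above background on 1 Cdx1+/+ and 2 Cdx1-/- arrays, with an adjusted p of 0.0523 when replicate number was a block. With normexp background correction the calls ended for Aadacl2, Clrn3, Dera, Gsdmcl2, H2al1j, Katnal2, Olfr1370, Tas2r105, Tas2r117, Vmn2r42 and Zfp94.

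In all, 3170 of 24338 genes passed limma's test in mTEC, with 1558 higher and 1612 lower in Cdx1-/- cells and a median absolute log2 difference of 0.62. All 3170 had the arrays of the genotypes apart, as did 38.3% of all tested genes, against 10% by chance. At least 2-fold, 164 were higher and 301 lower. At an unadjusted p under 0.05, 7595 genes stood against 1217 by chance, and 601 of those were at least 2-fold apart (220 higher, 381 lower), with 570 within slide 1, 180 with normexp, 356 with the strict filter on dim probes and 925 without a filter. With slide as a block 1777 genes passed (834 higher, 943 lower), and 1851 passed within slide 1 (865 higher, 986 lower). Leaving out 1 array gave 1319 to 1851 genes, the lowest without Cdx1+/+ replicate 3.

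Genes of absorptive enterocytes, the nutrient-absorbing cells of the gut lining, fell together in Cdx1-/- mTEC. Of 39 tested, 23 fell, 2 rose and 14 did not pass, and the median log2 difference was −0.68. The sucrase-isomaltase gene Sis fell by 1.85 (SE 0.09, adjusted p = 0.00107), from 0.57 ± 0.03 to −1.28 ± 0.09 (SD, n = 3 each). The liver-type fatty acid-binding protein gene Fabp1 fell by 1.44 (SE 0.08, adjusted p = 0.00198), the galectin gene Lgals4 by 1.54 (SE 0.11), and the nuclear receptor gene Hnf4a by 1.19 (SE 0.08, both adjusted p = 0.00243). The 2 that rose, chosen after their values were seen, were Gucy2c (0.51), the receptor for guanylin, and the peptidase gene Dpp4 (0.59). With adjustment over the list alone, 31 fell and 2 rose. The list passed camera's test (adjusted p = 4.9e-16), within slide 1 too (median −0.65, adjusted p = 1.71e-15), and with an estimated correlation (adjusted p = 0.0493).

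Genes described as Cdx targets in intestine were shifted down as a list, and 16 of the 21 tested are in another list. Of these, 9 fell, 1 rose and 11 did not pass, with a median of −0.42. Besides Sis, Lgals4 and Hnf4a, the microvillus gene Vil1 fell by 1.07 (SE 0.11, adjusted p = 0.00456). The riser, the transcription factor gene Klf4 (0.52), was chosen after its value was seen. In an adjustment over the list alone 14 fell and 1 rose. The list passed camera's test (adjusted p = 9.99e-08), and its adjusted p was 0.0493 with an estimated correlation. Within slide 1 the median was −0.42. Without the genes that these arrays show as enriched in intestine, a choice made after seeing the data, the median was −0.068 and the call ended (adjusted p = 0.488; range over the alternatives 6.28e-09 to 0.488).

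Goblet, Paneth and enteroendocrine genes passed camera's test as a list shifted down at its preset correlation, but not at an estimated one. Of 30 tested, 11 fell, 1 rose and 18 did not pass, with a median of −0.28. The hormone gene Sct (secretin) fell by 0.99 (SE 0.08, adjusted p = 0.00321), the goblet cell trefoil peptide gene Tff3 by 0.58 and the somatostatin gene Sst by 0.51, while Tph1, which encodes the enzyme that starts serotonin synthesis in gut, rose by 0.61 (SE 0.09, adjusted p = 0.0116). When adjusted over the list alone, 13 fell and 3 rose. The list had a camera adjusted p of 0.000488, and 0.20 with an estimated correlation. Of 16 crypt and Wnt target genes, 2 rose, Tnfrsf19 by 0.63 (adjusted p = 0.0139) and the Polycomb gene Bmi1 by 0.55 (adjusted p = 0.0323), and 14 did not pass, and adjusted over the list alone 2 rose and 0 fell. Their median was 0.12 (camera adjusted p = 0.0466; adjusted p = 0.258 with an estimated correlation). This call ended with slide as a block (median 0.11, adjusted p = 0.0501) and under several other settings.

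Aire-dependent and liver genes, transcripts of other organs that mTEC also express, passed camera's test as lists shifted down at its preset correlation, but not at an estimated one. Of 12 genes described as dependent on Aire, the regulator of ectopic expression, 7 fell and 5 did not pass, with a median of −0.44. The insulin gene Ins2 fell by 1.25 (SE 0.10, adjusted p = 0.00252), the casein gene Csn1s2a by 0.54 and the spermine-binding protein gene Sbp by 0.59. On adjustment over the list alone 8 fell. Its camera adjusted p was 2.44e-05, and 0.258 with an estimated correlation, and 9 of the 12 are in another list. Of 25 liver genes, 10 fell and 15 did not pass, with a median of −0.43. The fibrinogen chain genes Fgb (−1.17, adjusted p = 0.00307), Fgg (−0.96) and Fga (−1.07) fell. Among liver genes adjusted over the list alone, 15 fell and 1 rose. For them camera's adjusted p was 1.94e-05, and 0.20 with an estimated correlation. Within slide 1 the medians were −0.43 for Aire-dependent and −0.47 for liver genes.

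Among 20 milk, saliva and urine protein genes, 5 fell and 15 did not pass, with a median of −0.17. The submaxillary gland gene Smr3a fell by 1.52 (SE 0.20, adjusted p = 0.00833), above background on 2 of 3 Cdx1-/- arrays, and the whey protein gene Wap by 0.57. Of these 20, adjusted over the list alone, 6 fell. Camera's adjusted p was 0.000177, and 0.20 with an estimated correlation. Of 21 brain and retina genes, 3 fell and 18 did not pass, with a median of −0.23. The glutamate receptor subunit gene Grin1 fell by 0.66 (SE 0.10, adjusted p = 0.0105). Snap25, a synaptic vesicle fusion gene, was at −0.93 and did not pass (adjusted p = 0.0579). Gap43 and Mag, of growing axons and myelin, passed at −0.40 and −0.43 but not with replicate number as a block (adjusted p = 0.0749 and 0.0708). Of all 21, adjusted over the list alone, 5 fell and 1 rose. The shift passed camera's test with an adjusted p of 0.00902, and 0.258 with an estimated correlation. Within slide 1 the medians were −0.17 for milk, saliva and urine genes and −0.23 for brain and retina genes.

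Of tuft cell and cornified keratinocyte genes, those that passed limma's test rose, and both lists passed camera's test at its preset correlation but not at an estimated one. Of 17 genes of tuft cells, the chemosensory cells of gut and thymus, 9 rose, none fell and 8 did not pass, with a median of 0.48. The actin-binding protein gene Avil rose by 1.06 (SE 0.13, adjusted p = 0.00696), the leukotriene synthesis gene Alox5 by 0.99, the taste transduction channel gene Trpm5 by 0.84 (SE 0.14, adjusted p = 0.0146) and the gustatory G protein gene Gnat3 by 1.06. Adjusted over the list alone, 12 rose and 0 fell. Camera's adjusted p was 1.94e-05, and 0.258 with an estimated correlation. Of 21 cornified keratinocyte genes, which mTEC also express after their Aire stage, 7 rose and 14 did not pass, with a median of 0.39. The protease inhibitor gene Spink5 rose by 1.11 (SE 0.11, adjusted p = 0.00362), the keratin gene Krt10 by 1.08, the calmodulin-like gene Calm4 by 0.82 and the involucrin gene Ivl by 0.72. Adjusted over the list alone, 11 rose and 1 fell. Camera's adjusted p was 0.000177, and 0.20 with an estimated correlation. Within slide 1 the medians were 0.46 for tuft and 0.42 for keratinocyte genes.

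Genes that mark mature mTEC moved little. Of 20, the chemokine gene Xcl1 fell by 0.96 (adjusted p = 0.00932), the costimulatory ligand gene Cd86 rose by 0.36 (adjusted p = 0.0318) and 18 did not pass. Chosen after their values were seen, Aire was at −0.03 (adjusted p = 0.874) and Fezf2, another regulator of ectopic expression, at 0.00 (adjusted p = 0.996). Adjusted over the list alone, 1 rose and 1 fell. The median was −0.18 (camera adjusted p = 0.0390; adjusted p = 0.611 with an estimated correlation), and the call ended within slide 1 (median −0.14, adjusted p = 0.0908). Among lists that did not pass, immature mTEC genes had 0 of 6 past limma's test and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.314; 1 fell when adjusted over the list alone). In cortical thymic epithelium genes only Il7 rose (0.58) out of 13 (camera adjusted p = 0.46; adjusted over the list alone, 2 rose and 1 fell). In the MHC class II pathway only H2-Ob rose (0.48) out of 9 (camera adjusted p = 0.698; adjusted over the list alone 1 rose), and in the class I pathway only Tap1 (0.46) out of 14 (camera adjusted p = 0.802; 0 adjusted over the list alone). For class I genes the median was −0.04 while the mean was 0.01.

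Hox genes went both ways. Of 28, 6 rose and 2 fell, among them Hoxa3 and Hoxa2 (1.20, adjusted p = 0.00832), Hoxc11 (0.92, adjusted p = 0.00498) and Hoxd4 (−1.17, adjusted p = 0.00326), without a shift of the list (median 0.17, camera adjusted p = 0.22). Adjusted over the list alone, 8 rose and 3 fell. Of 32 pancreas genes, 8 fell and 1 rose, with Ins1 at −1.29, the syncollin gene Sycn at −0.60 and the chymotrypsinogen gene Ctrb1 at −0.88, but the list did not pass (median −0.01, mean −0.19, camera adjusted p = 0.157; adjusted over the list alone, 8 fell and 2 rose). Fry gave the pancreas and stomach lists an adjusted p of 0.0318 each, both down. Of 18 stomach genes, 4 fell, Anxa10 (−0.55), the gastrokine gene Gkn3 (−0.76), the pepsinogen gene Pgc (−0.98) and Tff2 (−0.45), without passing as a list (median −0.16, camera adjusted p = 0.102; adjusted over the list alone, 6 fell and 3 rose). Of 29 striated muscle genes, 4 fell and 2 rose, with the troponin gene Tnnc1 at −1.15 and the acetylcholine receptor gene Chrnd at 0.68 (median −0.22, camera adjusted p = 0.0551; adjusted over the list alone, 5 fell and 3 rose). Of 16 germ cell genes, 3 fell and 2 rose, with the helicase gene Ddx4 at −0.72 and the protamine gene Prm2 at 0.59 (median −0.24, camera adjusted p = 0.22; adjusted over the list alone, 3 fell and 2 rose).

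Markers of other cells that a sort could carry over did not pass camera's test as lists. Fry, which asks only whether a list's own genes move one way on balance, gave the mesenchymal list an adjusted p of 0.0318 and the endothelial list one of 0.0439, both down. Of 18 thymocyte genes 1 fell, the pre-T cell receptor gene Ptcra (−0.48; camera adjusted p = 0.91, and 1 adjusted over the list alone; the median was −0.03 and the mean 0.01). Of 7 B cell genes, Blk (0.66) and Cd79b (0.56) rose and Ebf1 (−0.63) fell (camera adjusted p = 0.802; adjusted over the list alone, 4 fell and 3 rose; the median was −0.29 while fry's direction was up). Of 19 dendritic cell and macrophage genes, the mannose receptor gene Mrc1 fell by 1.42 and the lysozyme gene Lyz2 rose by 0.93 (camera adjusted p = 0.157; the same 1 and 1 adjusted over the list alone). Of 10 mesenchymal genes, 1 fell, the receptor gene Pdgfrb (−0.78), which lies within 10 Mb of Cdx1 (camera adjusted p = 0.46; 1 adjusted over the list alone). Of 9 endothelial genes 2 fell, Robo4 (−0.45) and Tie1 (−0.61; median −0.44, camera adjusted p = 0.0662; adjusted over the list alone, 4 fell and 1 rose). Of 27 cell cycle genes only the kinesin gene Kif11 fell (−0.66; camera adjusted p = 0.639, and 1 adjusted over the list alone). Of 22 immediate-early and heat shock genes only the co-chaperone gene Dnajb1 rose (0.37; camera adjusted p = 0.521, and 0 adjusted over the list alone), and of 30 interferon response genes 0 passed limma's test either way and 10 had an unadjusted p under 0.05 (camera adjusted p = 0.424; Usp18 and Ifit1 came nearest, with adjusted p = 0.0677 and 0.0688). The erythroid list had 4 measured genes, too few for a list test, of which Alas2 fell by 0.55 (adjusted p = 0.0152). The sex-linked list had 4 as well, with Xist at 0.11 (adjusted p = 0.891).

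**Figure D2:**
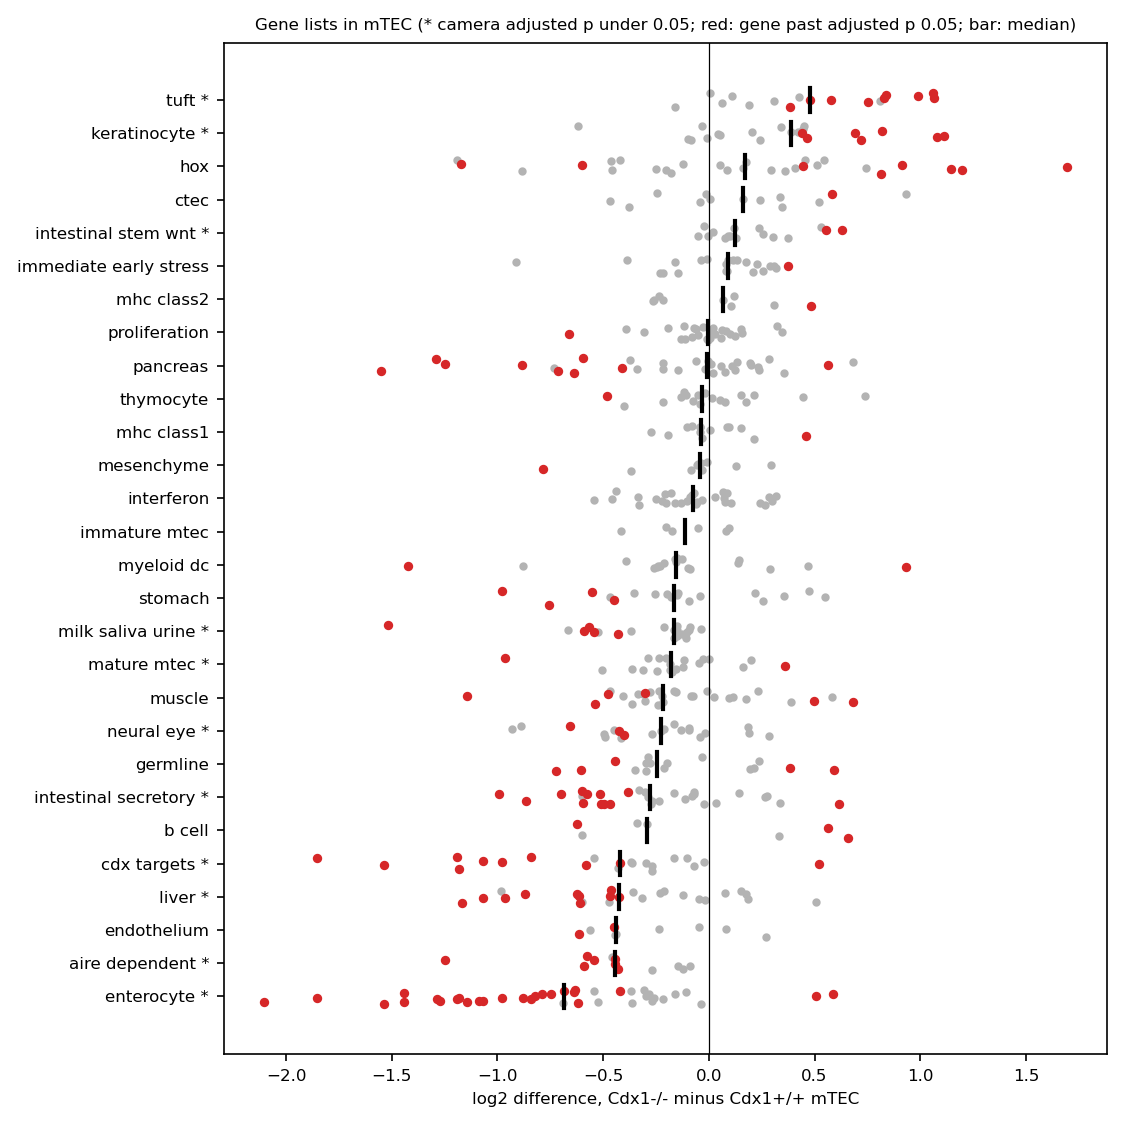
Log2 difference between Cdx1-/- and Cdx1+/+ mTEC (x axis) of each measured member of the 28 tested gene lists (y axis, with vertical jitter to part the points), where red points passed the adjusted test, grey points did not, black bars are list medians and stars mark lists that passed camera's test. The enterocyte median lies lowest at −0.68 and the tuft median highest at 0.48.

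Genes enriched in intestine on these same arrays were shifted down in Cdx1-/- mTEC. Of 958 genes at least 8-fold higher in SIEC than in mTEC and tested in mTEC, 187 fell, 49 rose and 722 did not pass. The median was −0.14, against 0.01 for the other 23380 genes, and the set passed camera's test (p = 4.47e-06; p = 0.00674 with an estimated correlation). Without the fixed intestinal lists, a choice made after seeing the data, 899 genes had a median of −0.13 and passed camera's test too. Within slide 1 the set passed with a median of −0.14. In the authors' table it passed with a median of −0.048. Lowering the enrichment to 4-fold ended the call (median −0.01).

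Near Cdx1, differences in mTEC were larger but went both ways. Besides Slc6a7, Cep76 and Slc27a6, the genes that moved within 10 Mb included, chosen after their values were seen, Ccbe1 (1.31), Rab27b (1.10) and Sh3tc2 (0.98), which were higher in Cdx1-/- cells, and Gnal (−0.98), Tubb6 (−0.96) and Il17b (−0.87), which were lower. Of 143 tested genes in the window, 22 fell, 15 rose and 106 did not pass, and the window as a set did not pass camera's test (median −0.01). Differences of at least 2-fold that passed the test made up 6.99% of the window (10 genes) against 1.88% of the other genes (Fisher's exact test, p = 0.000438). The 10 include adjacent genes without ordinary symbols, at −0.77 to −0.72 Mb from Cdx1, which fell together by log2 differences of −1.54, −4.22 and a fitted −4.25. Fisher's test counts such neighbours as independent. At an unadjusted p under 0.05, 64 genes or 44.8% of the window passed, against 31.1% elsewhere, and 53 did within slide 1.

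**Figure D3:**
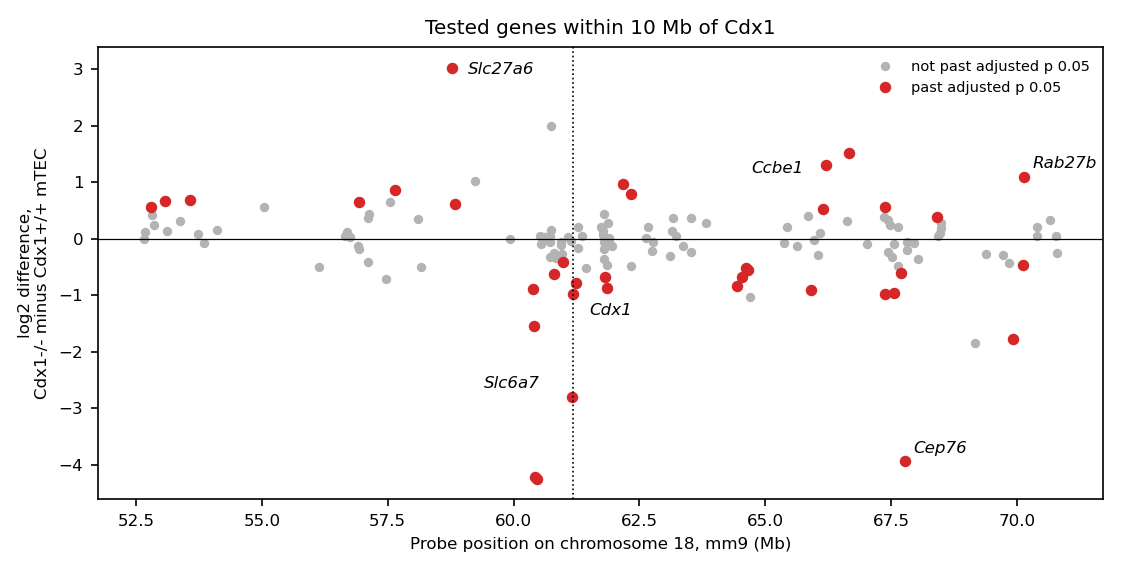
Log2 difference between Cdx1-/- and Cdx1+/+ mTEC (y axis) of the 143 tested genes within 10 Mb of Cdx1, by probe position on chromosome 18 in mm9 (x axis, Mb), with red points past the adjusted test, grey points not past it and a dotted line at Cdx1. Slc6a7 stands beside Cdx1 at −2.80, and Cep76 and Slc27a6, drawn at their fitted values, have only bounds of at least 3.87-fold and 3.94-fold. Some unlabelled points also have only bounds. The lowest points are unlabelled neighbouring genes, at a fitted −4.25 (at least 6.92-fold) and at −4.22.

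Intestine and mTEC differed for most genes. SIEC had far more of the urea cycle gene Otc (at least 423-fold), Smlr1 (at least 317-fold), the lectin-like gene Clec2h (940-fold), the Paneth cell phospholipase gene Pla2g2a (623-fold), the retinol-binding protein gene Rbp2 (433-fold, above background on 4 of 6 mTEC arrays), the claudin gene Cldn15 (431-fold), the peptidase gene Naaladl1 (399-fold), Erich4 (328-fold, also on 4 of 6) and the lactase gene Lct (317-fold). The Paneth cell defensin genes Defa26 (383-fold), Defa40 (323-fold) and Defa-ps1 (312.5-fold) were also higher, and such near-identical copies can share probe signal. In mTEC the keratin gene Krt17 was higher by at least 3443-fold, Alox12e by at least 2710-fold, the thymic gene Tbata by at least 1576-fold and the fatty acid-binding protein gene Fabp4 by at least 1007-fold. Also higher there were the chemokine gene Ccl19 (at least 997-fold), Cyp2a4 (at least 921-fold), the acute phase gene Saa3 (at least 790.5-fold), Dapl1 (at least 745-fold), Sncg (at least 615-fold), the trefoil gene Tff1 (at least 492-fold), the adhesion gene Vcam1 (at least 461-fold) and the airway gene Bpifa1 (at least 461-fold). The probe used for each of these 12 was not well above background on either intestine array, though another probe of Ccl19 and of Tbata was on 1 of them. The limma adjusted p of the 24 genes ranged from 2.38e-09 to 5.35e-07.

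Of the fixed lists, 38 of 40 enterocyte genes (median 6.16), 19 of 22 Cdx targets (5.66), 18 of 32 secretory genes (3.05), 7 of 16 crypt genes (1.35) and 17 of 28 cell cycle genes (2.09) were higher in SIEC by at least 4-fold and past the test. The mTEC side held 20 of 21 keratinocyte genes (−6.93), 4 of 6 immature mTEC genes (−7.08), 10 of 12 Aire-dependent genes (−6.71), 14 of 20 mature mTEC genes (−4.21), 16 of 18 stomach genes (−5.21), 15 of 20 milk, saliva and urine genes (−4.67), 23 of 29 muscle genes (−4.54) and 13 of 16 germ cell genes (−4.05). In all, 8419 of 25273 genes passed limma's test at 4-fold or more, with 3382 higher in SIEC and 5037 higher in mTEC, and 21249 passed at any size. Each intestine group has 1 array, so the spread comes mostly from mTEC. Both intestine arrays lie on slide 2 with only 1 mTEC array, so tissue and slide largely go together in this comparison. With a strict filter on dim probes 3449 genes passed, 2444 higher in SIEC and 1005 higher in mTEC, and with normexp 4047 passed. The split also depends on the scaling: 40.2% of the genes were higher in SIEC here, 34.3% after quantile normalization (2876 against 5522) and 55.3% in the authors' table (5266 against 4254), where the median of all genes shifted by 0.46, 0.10 and 0.90.

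Between the intestine arrays, lymphocyte, macrophage, mesenchymal, interferon and enterocyte genes were higher on the array labelled Cdx1-/-, and tuft, cell cycle and pancreas genes were lower. There is no replicate, so these are values of 2 pools, without a test. The lymphocyte antigen gene Ly6m was 63.6-fold higher, the ectonucleotidase gene Nt5e 32.4-fold, Clca4a 27.3-fold and the adenosine deaminase gene Ada 17.3-fold. Slc28a2, a nucleoside transporter gene, was 9.45-fold higher, Mid1 8.55-fold, the myelin gene Pmp22 7.91-fold, Enpp3 7.52-fold, the smooth muscle myosin gene Myl9 7.46-fold, the macrophage scavenger receptor gene Stab1 7.40-fold, the chemokine gene Ccl4 7.09-fold and the kinase gene Sgk2 6.83-fold. The phospholipase gene Pla2g4c was 17.0-fold lower and the goblet cell gene Retnlb 15.8-fold. The gasdermin genes Gsdmc3, Gsdmc4 and Gsdmc, close copies that can share probe signal, were 5.25-fold, 4.97-fold and 4.82-fold lower. Bex4 was 5.87-fold lower, the calcium-binding protein gene S100g 5.09-fold, the iron exporter gene Slc40a1 4.81-fold, Alox5 4.33-fold, the water channel gene Aqp8 4.31-fold and the lipase gene Pnliprp1 4.12-fold.

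Enterocyte genes had a median of 0.65 across this pair (percentile 100 among random lists), with the apolipoprotein gene Apoc3 at 1.76 and the brush border peptide transporter gene Slc15a1 at least 3.31-fold higher, and 9 of 39 at least 2-fold higher and 1, Aqp8, lower. T cell and thymocyte genes had a median of 1.31 (percentile 100), with Cd8a at 1.88 and Cd4 at 1.79, dendritic cell and macrophage genes 0.99 (percentile 100), with Tyrobp at 2.02, and interferon genes 0.69 (percentile 100), with Ifit1 at 1.49. The 7 mesenchymal genes above background on at least 1 of these arrays, with 4 on both and so too few for a list, were all higher, Fbn1 at least 3.98-fold, Acta2 at least 4.58-fold, Tagln by 1.43 and Col1a2 by 1.26. Mature mTEC genes stood at 0.27 (percentile 99.4), immediate-early and heat shock genes at 0.25 (98.8) and MHC class II genes at 0.25 (97.4). Tuft genes had a median of −1.53 (percentile 0), with Gfi1b at −1.91 and Dclk1 at −1.65, cell cycle genes −0.53 (percentile 0), with Top2a at −1.08, pancreas genes −0.63 (percentile 0), Hox genes −0.59 (percentile 0.16), and crypt and Wnt target genes −0.32 (percentile 0.24), with the stem cell receptor gene Lgr5 at −0.90. Cortical thymic epithelium genes were at −0.12 (34.2). Secretory genes (0.15, percentile 99.8), Cdx targets (0.13, 99.1), liver (0.10, 87.5), brain and retina (0.13, 81.3), keratinocyte (0.08, 63.4) and MHC class I genes (0.05, 87.0) had small medians. The authors' table multiplies each array by a constant, which moves all genes alike and turns the sign of these 6 medians, while relative to the median of all genes they were 0.19, 0.17, 0.14, 0.16, 0.12 and 0.09 both here and in that table. The arrays differed in sex-linked transcripts: Xist read 1.13 and −5.34 and the Y-linked gene Eif2s3y −5.72 and 2.37 on the arrays labelled Cdx1+/+ and Cdx1-/-. Ddx3y, also Y-linked, read −5.53 and 1.19. Probes of the Y-linked gene Uty went both ways, 1 at −1.71 and −5.12 and another at −5.63 and −2.63. Apart from 1 Uty probe, these values are those of a female pool labelled Cdx1+/+ and a male pool labelled Cdx1-/-. Sex and label therefore cannot be told apart in this pair.

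Of 19132 genes above background on at least 1 intestine array, 1362 differed by at least 2-fold, 970 higher and 392 lower on the array labelled Cdx1-/-, and with normexp 388 did (259 higher, 129 lower). Among the 17156 above background on both, 783 did, 583 higher and 200 lower. The higher share was 71.2% here, 62.6% after quantile normalization and 45.8% in the authors' table, where the median of all genes shifted by −0.25.

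Genes that differed by genotype in mTEC did not differ in the same direction in the intestine pair more often than others. Sis fell in mTEC while its signal was higher on the array labelled Cdx1-/-, and Alox5 rose in mTEC while it was lower there. Across 16650 genes above background in both tissues, Spearman's rho between the differences was −0.188, across genes that are not independent replicates, and it was −0.0217 without the filter on dim probes. Of 1651 genes called in mTEC, 665 or 40.3% had the same sign in SIEC (95% binomial interval 37.9% to 42.7%, exact, for counting error only), against 41.9% in random gene sets matched on expression (percentile 7.4). The difference between the tissues itself was not tested, since each intestine label has 1 pool, and pools can differ in other ways than genotype.

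**Figure D4:**
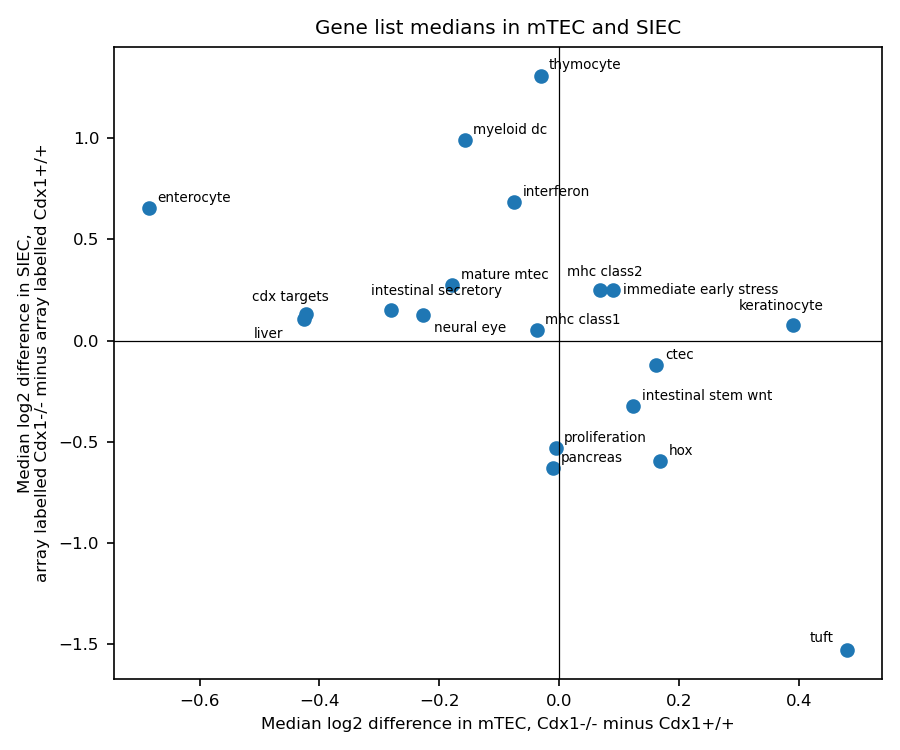
Median log2 difference of each gene list measured in both tissues, between Cdx1-/- and Cdx1+/+ mTEC (x axis, 3 arrays each) and between the single intestine arrays labelled Cdx1-/- and Cdx1+/+ (y axis, no replicate). Each median is over the members measured in that tissue, so the genes of the axes differ, with 17 and 12 for the tuft list. Over the tuft genes measured in both tissues the medians were 0.53 and −1.26. Enterocyte genes lie at −0.68 in mTEC and 0.65 in SIEC, tuft genes at 0.48 and −1.53, and the SIEC medians of the secretory, Cdx target, liver, brain and retina, keratinocyte and MHC class I lists change sign with the array constants of the authors' table.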

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

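The tests of dim genes, of slide, of the share of medullary cells, of exchanged labels and of strain variants and the counts over splits of the arrays were chosen only after the results were seen, and so was the rule for genes and lists that go opposite ways in the tissues. The test without sex chromosomes was written before.

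In Cdx1-/- mTEC, enterocyte genes had a median log2 difference of −0.68. Weaker detection of dim genes on the Cdx1-/- arrays is argued against, because the 22 enterocyte genes above the 75th percentile had a median of −0.885 (95% bootstrap interval over genes −1.19 to −0.618). The bootstrap intervals here resample genes and do not measure the spread between pools. The slide of Cdx1-/- replicate 1 is argued against as well, with a median of −0.65 within slide 1 (camera adjusted p = 1.71e-15, range over the alternatives 3.27e-19 to 0.0493). So are fewer medullary epithelial cells in the sorts as the cause of the whole fall, since mature mTEC genes had a median of only −0.18 (95% bootstrap interval over genes −0.24 to −0.08). That interval is wholly negative, so a smaller contribution from fewer medullary cells is not argued against. Lower expression per cell, a smaller share of an enterocyte-like subset of mTEC, and variants of the mixed background were not tested and may each contribute. The 6 arrays make 10 splits, too few for a share under 0.05.

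In the intestine pair Cdx1 was higher on the array labelled Cdx1-/-, and the difference between the tissues' contrasts was 2.59. The Spearman correlation between the tissues' differences was −0.188 (−0.212 to −0.0217 over the alternatives). Without genes on X and Y it was still −0.188, over 16099 of 16650 genes. The correlation did not rest on those genes, but so few dropped out that it could hardly change. Xist was well above background only on the intestine array labelled Cdx1+/+, and Eif2s3y (at least 69.9-fold) and Ddx3y (at least 30.8-fold) only on the other. That is the pattern of a female against a male pool, though 1 Uty probe went the other way. Sex and label therefore cannot be told apart in this pair, and an effect of sex was not tested. If the labels of the 2 intestine arrays were exchanged, genes linked to Cdx1 would tend to have opposite signs in the tissues. Of 21, 14 did, or 66.7% (exact binomial p = 0.189, exact interval 43.0% to 85.4%), against 59.6% of 1630 genes elsewhere. The 21 include Cdx1 itself, whose reversal prompted the test. The linked genes Cep76 and Ldlrad4 also had opposite signs, but were above background on only 1 intestine array and so were left out. In mTEC Cep76 was well above background on 3 of 3 Cdx1+/+ and 0 of 3 Cdx1-/- arrays. In the intestine pair its log2 signal was higher by a fitted 3.66 on the array labelled Cdx1-/-. The filter drops any gene detected in 1 genotype alone, so the test could not use Cep76. It is 1 gene, and the labels were not decided from it. Exchanged labels, an effect of the difference in sex, an allele that leaves the probed part of the transcript, and a different response of intestine therefore remain open.

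Within 10 Mb of Cdx1, 6.99% of genes were called at 2-fold or more in mTEC, against 1.88% elsewhere (Fisher's exact test, p = 0.000438). Some of them are adjacent genes that fell together, which this test counts as independent. No technical explanation is argued against here. Strain variants carried along with the targeted allele would give such a share and may account for it, either by altered expression or by altered binding of probes. A local effect of the altered Cdx1 locus on its neighbours was not tested and would give the same excess. Siglec15 and Katnal2 lie farther out on chromosome 18, and whether they carry strain variants linked to the allele was not tested.

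The results below are given because every Cdx1-/- mTEC array lay to 1 side of every Cdx1+/+ mTEC array while the intestine pair went the other way by label. Only the Cdx genes and those named for the largest changes in mTEC or the intestine pair were looked through, where they were well above background on both intestine arrays and on at least 2 arrays of an mTEC group. The difference was not tested, since each intestine label has 1 pool and pools can differ in other ways than genotype. Groups of 3 arrays were not tested for outlying values. The log2 difference in SIEC minus that in mTEC was 5.30 for Clca4a, 4.37 for Ada, 3.77 for Slc6a7, 3.67 for Stab1, 3.03 for Adam19, 2.63 for Cdhr5 and 2.59 for Cdx1, which were lower in Cdx1-/- mTEC, and −3.10 for Alox5 and −2.92 for Bex4, which were higher there. Of these Clca4a, Ada and Bex4 did not pass limma's test in mTEC (adjusted p = 0.0749, 0.113 and 0.0953), and 38.3% of all tested genes had the mTEC arrays apart in that way. Clrn3 met the rule with a fitted 3.23 whose size is not supported, because it was well above background on no Cdx1-/- mTEC array.

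The same rule was applied to the median of each list over its members measured in both tissues, for lists with at least 5 of them. Enterocyte genes differed by a median of 1.40 (39 genes), Cdx targets by 0.58 (21), liver genes by 0.58 (14), secretory genes by 0.42 (30), mature mTEC genes by 0.31 (12) and brain and retina genes by 0.19 (6), all lower in Cdx1-/- mTEC. Tuft genes differed by −1.71 (12) and crypt and Wnt target genes by −0.66 (16), both higher there. In the authors' table the intestine medians of the secretory, Cdx target, liver and brain and retina lists change sign with the array constants, so only relative to the median of all genes do these 4 lists go opposite ways on both scales.

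Of the 10 splits of the mTEC arrays, the real one gave 3170 genes and the highest other 0, with 1 split as large. For genes at an unadjusted p under 0.05 and at least 2-fold apart the values were 601 and 72 (1 as large), for genes near Cdx1 64 and 8 (1), and for lists 11 and 14 (3). Absolute medians, real and highest other, were 0.68 and 0.33 for enterocyte genes, 0.42 and 0.26 for Cdx targets, 0.28 and 0.15 for secretory genes, 0.44 and 0.23 for Aire-dependent genes, 0.43 and 0.21 for liver, 0.23 and 0.20 for brain and retina, 0.17 and 0.13 for milk, saliva and urine, 0.39 and 0.27 for keratinocyte, 0.48 and 0.32 for tuft, 0.18 and 0.13 for mature mTEC and 0.14 and 0.07 for intestine-enriched genes, each with 1 as large. For crypt and Wnt target genes they were 0.12 and 0.13, with 2 as large. Only 4 of the splits part all 3 replicate pairs as the real one does, and the others of these gave at most 0 genes, while 6 part only 1 pair. Slide 2 held only Cdx1-/- replicate 1 of the mTEC arrays, so no split can follow the slide and the splits do not test it. With 10 splits the smallest share is 0.1, too few for a share under 0.05. Every other split mixes the genotypes within both of its groups. It so keeps part of the genotype difference and adds the rest to the spread, which lowers its gene counts. The values of the other splits are therefore not those of arrays without a genotype difference.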

How the results depend on the processing

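The alternatives without intestine-enriched genes, without genes near Cdx1, without the fixed intestinal lists and with intestine-enriched genes above background on all 6 mTEC arrays were chosen only after the data were seen, and the others were planned. Cdx1 in mTEC kept its direction and stayed past the threshold under all 16 of its alternatives (−1.02 to −0.93, adjusted p 0.00121 to 0.0179), as did the enterocyte list under its 18 (−0.72 to −0.60, adjusted p 3.27e-19 to 0.0493). These counts hold the fit within slide 1 and the one without Cdx1-/- replicate 1 apart, though they are the same fit. No named gene or list that passed its test changed direction. The majority among counted genes turned from mTEC to SIEC between tissues with the authors' table and the strict filter, from higher to lower in the intestine pair with the authors' table, and from lower to higher in mTEC with the strict filter (1835 higher, 1801 lower), with a plain 2-sample test, with trend and robust eBayes and without intestine-enriched genes. The median of genes near Cdx1, which did not pass, ranged from −0.052 to 0.037, and 6 list medians of the intestine pair changed sign in the authors' table. For single genes named in mTEC, 1927 values kept their side of the threshold and 196 lost and 53 gained a call. For tissue genes 368 kept theirs, and for intestine pair genes and lists 171 values moved by less than the SD of their probes between mTEC replicates and 87 by more. With replicate number as a block Cdx1 was at −0.98 (adjusted p = 0.0161) and 3587 genes passed limma's test. With normexp 2097 genes passed in mTEC (1021 higher), 180 genes were at an unadjusted p under 0.05 and 2-fold, crypt and Wnt genes were at 0.10 (adjusted p = 0.0586), the tissues differed by 4047 genes (1821 higher in SIEC, 2226 in mTEC) and the intestine pair by 388 (259 higher, 129 lower). Without a filter on dim probes 1344 genes passed (607 higher, 737 lower) of 34963 tested, 925 were at an unadjusted p under 0.05 and 2-fold, crypt genes were at 0.12 (adjusted p = 0.0668) and Spearman's correlation of the tissues' differences was −0.0217. With a strict filter those counts were 356 at 2-fold, 3449 between tissues (2444 higher in SIEC, 1005 in mTEC) and 783 in the intestine pair (583 higher, 200 lower), where fewer genes enter. Quantile normalization gave crypt genes 0.10 (adjusted p = 0.0530), and the mean of a gene's probes 0.13 (adjusted p = 0.0996). The authors' table gave 5266 genes higher in SIEC than mTEC, 557 higher and 658 lower in the intestine pair and 37.6% of called genes with the same sign. Slide as a block gave 1777 genes (834 higher, 943 lower), crypt genes 0.11 (adjusted p = 0.0501) and mature mTEC genes −0.14 (adjusted p = 0.0868). Within slide 1 there were 1851 (865 higher, 986 lower) and mature mTEC genes at −0.14 (adjusted p = 0.0908), and array weights gave them −0.15 (adjusted p = 0.0817). A plain 2-sample test passed 1459 genes (782 higher, 677 lower). With an estimated correlation 2 lists passed, and calls ended for secretory (−0.28, adjusted p = 0.20), liver (−0.43, 0.20), milk, saliva and urine (−0.17, 0.20), keratinocyte (0.39, 0.20), Aire-dependent (−0.44, 0.258), brain and retina (−0.23, 0.258), tuft (0.48, 0.258), crypt (0.12, 0.258) and mature mTEC genes (−0.18, 0.611). Fry gave mature mTEC genes −0.18 (adjusted p = 0.0906). Over all alternatives the adjusted p of crypt genes ranged from 0.0246 to 0.258 and of mature mTEC genes from 0.00583 to 0.611. Intestine-enriched genes defined at 4-fold lost their call (−0.011). Without intestine-enriched genes Cdx targets were at −0.068 (adjusted p = 0.488) and crypt genes at 0.18 (adjusted p = 0.0638). At 4-fold or more the intestine pair differed by 182 genes (105 higher, 77 lower). Leaving out 1 array gave 1319 to 1851 genes (651 to 865 higher, 668 to 1006 lower): 1800, 1689 and 1319 without Cdx1+/+ replicates 1, 2 and 3, and 1851, 1837 and 1688 without Cdx1-/- replicates 1, 2 and 3. Crypt genes ranged from 0.086 to 0.22 and lost their call without Cdx1+/+ replicates 2 and 3 and Cdx1-/- replicate 2. Mature mTEC genes ranged from −0.20 to −0.14 and lost theirs without Cdx1+/+ replicate 2 and Cdx1-/- replicates 1 and 3. Spearman's correlation of the tissues' differences was −0.148 without Cdx1-/- replicate 1. Fewer arrays or genes enter by construction where arrays are left out or filters tightened, and for the other settings the cause was not tested. Signal over background limits the folds of dim probes to bounds.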

Other observations

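The test of neighbouring genes was written before its result was seen, and the genes in the next paragraph were chosen only after their values were seen.

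The gasdermin C cluster was lower in Cdx1-/- mTEC. Gsdmc3, a gene of gut epithelium, went from 3.41 to 1.46, a log2 difference of −1.95 (SE 0.09, limma adjusted p = 0.00107), Gsdmc from 1.93 to 0.29, a difference of −1.64 (SE 0.11, adjusted p = 0.00243), and Gsdmc4 from 1.83 to 0.29, a difference of −1.54 (SE 0.11, adjusted p = 0.00252), each lower in 3 of 3 arrays. The relatives Gsdma, at 0.31 (adjusted p = 0.0925), and Gsdmd, at −0.10 (adjusted p = 0.403), did not pass. In the intestine pair the same 3 genes were lower on the array labelled Cdx1-/-, at −2.39 for Gsdmc3, −2.27 for Gsdmc and −2.31 for Gsdmc4. They are near copies whose probes can share signal.

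A hypothesis was that genes changed in mTEC lie near others changed in the same direction, which may be if expression in these cells varies by chromosomal neighbourhood. Of 2350 called genes outside the Cdx1 window, 34.4% had a neighbour at 10 to 200 kb with another name root called in the same direction. Across 10000 reshufflings matched on expression the median was 31.4% and the 95th percentile 33.4% (permutation p = 0.0076). The excess over the median is small. Strain variants elsewhere in the mixed background would also give such neighbours and were not told apart from it.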
